A study of Mus musculus with 6 samples.

How the data were processed

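RNA from C2C12 cells, an established mouse myoblast line that is grown as dividing myoblasts in serum-rich medium and forms myotubes when serum is withdrawn, was measured on 6 single-colour Agilent mouse gene expression arrays. Per the labels, the cells were kept in medium with 10% serum and transfected at 70 to 80% confluence with siRNA given as "20 um" (the unit is printed as in the labels), 3 biological replicates with a negative control siRNA (siRNA-NC) and 3 with an siRNA against the long non-coding RNA Meg3 (siRNA-MEG3). The time between transfection and RNA extraction is not given in the sources used here.

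Per the file headers, the deposited scanner output was made with Agilent Feature Extraction 11.0.1.1 and holds, for each spot, a processed signal intensity that was background-subtracted and detrended within its own array, a median pixel intensity, a local background intensity and quality marks. The deposited table of the whole series holds the authors' values on a log2 scale for 30732 probes; every column had a median of 8.11 and followed the log2 processed signal of their arrays (r from 0.9991 to 0.9997), so their scale and direction were read from the data, and the exact between-array step used to make them stayed unknown. Per the labels, the authors averaged repeated probes and took a normalization factor from probes with an intensity of at least 30 in all samples.

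Control spots and spots marked as non-uniform or as population outliers were left out, the spots of a probe were averaged, and each array's log2 processed signal was expressed relative to its own 75th percentile over 39429 probes. Of these probes, 27234 were named through RefSeq accessions in a table of the GRCm38.p6 assembly and 12195 kept only the accession of the array design. The probe design was made on an older assembly, so no coordinates are given. A probe was kept where it was well above background on all arrays of at least 1 group and usable in both samples of each group, and the brightest kept probe stood for its gene. This left 21974 entries, 15296 with a gene name and 6678 with only an accession, all of which are called genes below.

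Depth on an array is its signal over background. The share of spots well above background was 70.1, 75.2 and 71.9% on siRNA-NC arrays 1 to 3 and 63.0, 69.3 and 62.8% on siRNA-MEG3 arrays 1 to 3. The 75th percentile of the processed signal was 1289, 2279 and 1232 on the siRNA-NC arrays and 1307, 1334 and 1237 on the siRNA-MEG3 arrays. No spot was saturated. The number of samples limits the precision.

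The arrays were compared with each other on 227 probes printed 10 times, each with at least 8 clean spots. siRNA-MEG3 arrays 1 and 3 shared the scatter of single spots around their probe means (r = 0.98, against -0.19 to 0.52 for the other 14 pairs) and held the same position on a slide, as repeat scans of 1 hybridised array do. siRNA-NC arrays 1 and 3 differed between probes by no more than the noise between spots (ratio of between-probe to within-probe variance 1.04), while siRNA-NC arrays 1 and 2 differed clearly (159.0). Each of these pairs was therefore averaged and counted as 1 sample, which left 2 samples per group. siRNA-MEG3 arrays 1 and 2 came close to each other as well (1.33) but differed beyond the spot noise, and were kept as 2 samples. That ratio cannot show that they held separate RNA, since siRNA-MEG3 arrays 1 and 3 gave 2.10. The 2 siRNA-MEG3 samples may therefore be technical replicates too. The design set before the data were examined had used all 6 arrays as 6 samples; the averaging was decided afterwards, when counts of calls without it had already been seen, and rests on the spot comparison and not on those counts. The fits without it are among the alternatives. Dark patches were blocks of 30 by 17 spots in which over 5% of spots read more than 4-fold below siRNA-NC. They took up 35.0% of siRNA-MEG3 array 1, which array 3 repeats, and 5.95% of array 2.

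Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 2-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. With 2 samples per group the fit had 2 residual degrees of freedom and a prior of 2.40. Shifts were tested in 28 gene lists, which were fixed before the data were examined and each had at least 5 measured members. The test was camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry tests its members against no change, so the 2 can differ. Named genes followed a rule set beforehand: Meg3 and its measured neighbours; the 10 largest increases and 10 largest decreases among genes past the threshold with a log2 fold change of at least 1 in size, no overlap between the groups' arrays and a proper gene symbol; and up to 4 members of each called list and of 8 set lists. Genes named outside that rule are marked as such, and 1 gene that the rule names is not reported here. Where no array of a group was well above background, a change is given as at least N-fold: the brighter group's mean against the dimmer group's mean of, on each array, the higher of the probe's own signal and the lowest signal well above background.

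On simulated data with the real means and the fitted variance prior for siRNA-MEG3 against siRNA-NC (21974 genes, 2 samples per group), 81 of 100 genes changed by 5 on the log2 scale were called, 1 of 100 changed by 2 was called, and 4 unchanged genes were called. In this simulation the fit thus found large changes and missed most smaller ones. It gave both groups the same variance and changed few genes. The real siRNA-MEG3 samples differed far less than the siRNA-NC samples, so these shares and the 4 false calls need not hold for the real fit.

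Alternatives set beforehand were normexp background correction with an offset of 50, quantile normalization, the labels' factor (taken as a median), the authors' values, no filter and a stricter filter on dim probes, the mean of a gene's probes, a variance trend, the replicate number as a block, leaving out each array, and a fold limit. The files hold no mean spot intensity, so normexp used the median intensity. Deviations of same-numbered samples from their group means did not go together (r = 0.01 over 22239 probes). The siRNA-MEG3 samples differed by little beyond spot noise, so this cannot tell whether the numbers pair the samples. The labels do not say that they do, and the main fit has no block. All siRNA-NC arrays came from 1 scan, and the siRNA-MEG3 arrays from 2 other scans of another slide. No scan held both groups, so no slide or scan term could be fitted, and slide and group cannot be told apart.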

Results

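Gene expression in C2C12 myoblasts was profiled after transfection with an siRNA against the imprinted long non-coding RNA Meg3 or with a negative control siRNA, to ask which transcripts differ when Meg3 is targeted. Each group had 3 arrays that the labels call biological replicates. siRNA-MEG3 arrays 1 and 3 behaved as 2 scans of 1 hybridised array, and siRNA-NC arrays 1 and 3 differed by less than the noise between spots, so each pair was counted as 1 sample. Every comparison below is between 2 siRNA-MEG3 and 2 siRNA-NC samples, and p-values measure the spread between these samples, part of which may be technical: siRNA-MEG3 arrays 1 and 2 differed between probes by an SD of only 0.06 on the log2 scale, against 0.55 for siRNA-NC arrays 1 and 2. All siRNA-NC arrays lay on 1 slide and all siRNA-MEG3 arrays on another, so slide and group cannot be told apart in any value that follows.

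**Figure D1:**
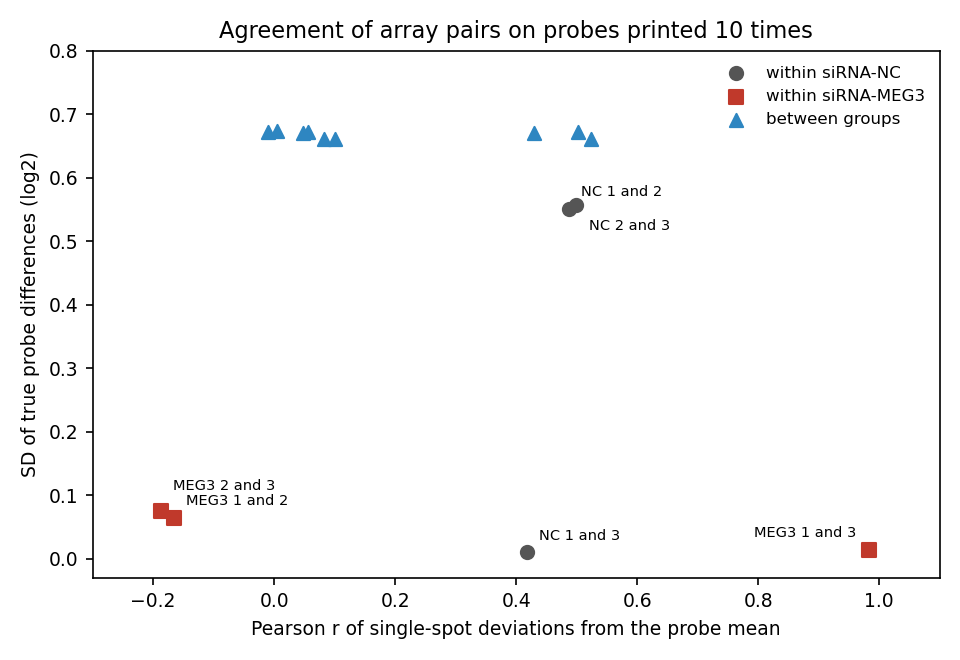
Each point is 1 of the 15 pairs of arrays; the x axis gives Pearson's r of single-spot deviations from the probe mean and the y axis the SD of probe differences on the log2 scale after removal of the spot noise, over 227 probes printed 10 times. The pair siRNA-MEG3 1 and 3 stands alone at r = 0.98, and siRNA-NC 1 and 3 lie near 0 on the y axis while siRNA-NC 1 and 2 lie at 0.55.

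Meg3 itself was too dim on these arrays for the knockdown to be measured. Of its 3 probes, none was well above background on any siRNA-MEG3 array, and 1 was so on siRNA-NC array 2 only. The processed signal of that probe, not scaled between arrays, was 11.6, 25.5 and 9.38 on siRNA-NC arrays 1 to 3 and 5.57, 10.8 and 5.47 on siRNA-MEG3 arrays 1 to 3. A second probe went the other way on siRNA-MEG3 arrays 1 and 3. It read 3.17, 3.54 and 4.92 on the siRNA-NC arrays and 13.6, 2.97 and 11.7 on the siRNA-MEG3 arrays. The third was mixed, at 14.1, 3.72 and 3.17 with siRNA-NC and 4.53, 11.4 and 4.45 with siRNA-MEG3. No fold change is given, since neither group was well above background as a whole, and the arrays do not check the labels in this respect. The 5 measured members of the imprinted Dlk1-Dio3 neighbourhood in which Meg3 lies did not pass the threshold (Dlk1 log2 fold change -0.94 ± 1.12 SE, Mirg -0.76 ± 0.43, Begain 0.44 ± 0.30, Wdr25 -0.18 ± 0.28, Dio3os 0.48 ± 0.23, n = 2 samples per group; limma adjusted p from 0.345 to 0.795). Mirg and Dio3os each passed in only 1 of 22 alternatives. Dlk1 was well above background on all 3 siRNA-NC arrays and on 1 of the 3 siRNA-MEG3 arrays, array 2, so its size is uncertain. Without array 2 Dlk1 stood lower, at -2.52. A lone siRNA-MEG3 sample below background then remains, so that size is uncertain too and no p-value is given for it.

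Genes of terminal muscle differentiation were far higher with siRNA-MEG3 than with siRNA-NC. Of 56 measured genes for myogenic differentiation, myoblast fusion and the sarcomere, 30 rose, none fell and 26 did not pass the threshold over all genes; adjusted over the list alone, 46 rose and 3 fell. The median log2 fold change of the list was 3.09, an 8.50-fold difference, or 2.85 with the 3 members below background in siRNA-NC set at their bounds. It was smaller, 2.04, with normexp background correction once the spots under a bright speck on 1 array were left out, a refit chosen after the data were seen. The list was called by camera (adjusted p = 9.79e-30 with the preset correlation), but not with an estimated correlation (adjusted p = 0.134). The fry test also called it (adjusted p = 0.00629).

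Among its members, the fast light chain gene Myl1 rose by 6.61 ± 0.32 (log2 ± SE, n = 2 per group; adjusted p = 0.0164), and its other probe gave 7.42. Casq2, which encodes a calcium-binding protein of the sarcoplasmic reticulum, rose by 5.79 ± 0.28 (adjusted p = 0.0164). The myosin heavy chain genes Myh1 and Myh8 rose by 6.01 ± 0.27 and 5.11 ± 0.25. Myh1 was well above background on 1 of 3 siRNA-NC arrays and Myh8 on 2 of 3, so these sizes are less certain. With normexp, the speck spots left out, Myh1 and Myh8 were smaller, at 3.70 and 3.12, and both still passed. Casq2 was also smaller in that refit and still passed. Embryonic myosin Myh3 rose by 7.06 ± 0.54 (adjusted p = 0.0229), with 6.67 on its other probe. The following members were picked from the list after their values were seen. Myog, the transcription factor that starts terminal differentiation, rose by 3.48 ± 0.23 (adjusted p = 0.0205), and the fusion genes Mymk and Mymx rose by 2.93 ± 0.34 and 3.81 ± 0.31 (adjusted p = 0.0465 and 0.0237). Some probes disagreed: Cacna1s rose by 3.45 on its brightest probe with -0.77 on the other, and Neb by 4.45 with -0.33.

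Genes of myoblast identity were not called by camera (adjusted p = 0.952, median 0.02). Fry, which tests members against no change and not against other genes, called the list (adjusted p = 0.00709). Of its 20 measured members 10 had a positive and 10 a negative fold change. None of the 20 measured members passed the threshold over all genes, and 2 rose and 2 fell when adjusted over the list alone. The member with the smallest p was Myf5, a determination factor of dividing myoblasts, at -2.86 ± 0.41 (adjusted p = 0.0659, not passing). Without siRNA-MEG3 array 2, which leaves a lone siRNA-MEG3 sample, Myf5 stood at -2.84. The determination factor Myod1 showed a 4.93-fold higher mean (log2 SE 0.43) and the cadherin gene Cdh15 stood at 1.42 ± 0.24, neither passing over all genes (adjusted p = 0.105 and 0.0899) and both singled out after their values were seen.

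Over the whole array, 351 of 21974 genes passed the threshold, 253 higher and 98 lower with siRNA-MEG3. All of these differed by at least 1 on the log2 scale. At an unadjusted limma p under 0.05 the count was 4271, against 1099 by chance if the samples were independent replicates. The siRNA-MEG3 samples may be technical replicates and slide follows group, so this excess does not count genes moved by the siRNA. Of the higher genes 229 had a gene name and 24 only an accession, while of the lower genes 47 had a name and 51 only an accession. Leaving out siRNA-NC array 1 gave a lower count of 61. Without siRNA-NC array 2 or siRNA-MEG3 array 2 a lone sample remains in a group. The spread then comes from the other group alone, so counts from these fits cannot show whether the calls rest on 1 array. The median of the sarcomere list was 2.88 without siRNA-NC array 2 and 3.10 without siRNA-MEG3 array 2, against 3.09 in the main fit. Of 39 named genes, 38 and 39 kept their direction in these fits. Without a filter on dim probes 33 were higher and 1 lower, with normexp background correction 0 in each direction (1102 at an unadjusted p under 0.05) and, once the spots under a bright speck on 1 array were left out, 239 and 150, so that 61.4% of calls were higher against 72.1% with the processed signal and the same 4 samples. With all 6 arrays counted as 6 samples, as first planned, 3906 genes were higher and 2131 lower.

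The 10 named genes with the largest increases included the muscle genes Myh3, Myl1, Myh1 and Pdlim3, a Z-disc protein gene that rose by 7.02 ± 0.23 (adjusted p = 0.0164). Tspan7, a tetraspanin gene, rose by 8.40 ± 0.33, and Alox5, the gene of arachidonate 5-lipoxygenase, by 7.31 ± 0.39 (adjusted p = 0.0164 for each). Vgll2, a cofactor of TEAD factors in skeletal muscle, was at least 205-fold higher by the processed signal and below background on all siRNA-NC arrays (adjusted p = 0.0164), and stood at a smaller log2 fold change of 5.25 with normexp, the speck spots left out. The neurofilament gene Nefl rose by 6.06 ± 0.32 and Tceal7 by 6.05 ± 0.21 (adjusted p = 0.0164 for each). Tspan7, Nefl and Tceal7 were well above background on 1 of 3 siRNA-NC arrays. In the same normexp refit Tspan7, Alox5 and Pdlim3 were smaller, at 6.06, 5.56 and 5.71. Nefl and Tceal7 stood at 3.67 and 3.95 there, and all of these genes still passed.

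The 10 named genes with the largest decreases had no list in common. Cbx7, a Polycomb group gene, was at least 14.8-fold lower and below background on all siRNA-MEG3 arrays (adjusted p = 0.0164). The same held for the cell growth gene Lyar (at least 10.3-fold lower), the Wnt pathway ligand gene Rspo3 (at least 8.22-fold) and Pdzrn4 (at least 3.81-fold), with adjusted p of 0.0299, 0.0340 and 0.0268. These bounds also refer to the processed signal: with normexp, the speck spots left out, Cbx7 stood at -1.94 and still passed, while Lyar, Rspo3 and Pdzrn4 stood at -1.56, -1.31 and -0.58 and did not (adjusted p = 0.0557, 0.0957 and 0.383). Serpinb1c stood at -3.39 ± 0.23 and Ccn3, a matricellular protein gene, at -3.25 ± 0.39 (adjusted p = 0.0205 and 0.0483), both above background on all arrays. Ccn3 kept a similar size but no longer passed without siRNA-NC array 1 (-3.14, adjusted p = 0.0740) or with outlier spots kept (-3.34, adjusted p = 0.0539). Ubxn4 stood at -3.72 ± 0.26 and H2-M10.1 at -3.60 ± 0.25 (adjusted p = 0.0205 and 0.0206). Fbxo25 and Tbc1d14 stood at -3.68 ± 0.26 and -3.67 ± 0.28 (adjusted p = 0.0206 and 0.0229), but their other, brighter probes, which had outlier spots, gave -0.11 and -0.26. With outlier spots kept, those probes stood for the genes and neither gene passed (adjusted p = 0.866 and 0.671). Ubxn4 was well above background on 2 of 3 siRNA-MEG3 arrays, and H2-M10.1 and Tbc1d14 on 1 of 3, so these sizes are less certain. With normexp, the speck spots left out, Ubxn4, H2-M10.1, Fbxo25 and Tbc1d14 were smaller, at -2.32, -2.04, -2.52 and -2.25. Serpinb1c and Ccn3 stood at -2.67 and -2.98 there, and all of these genes passed in that refit.

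**Figure D2:**
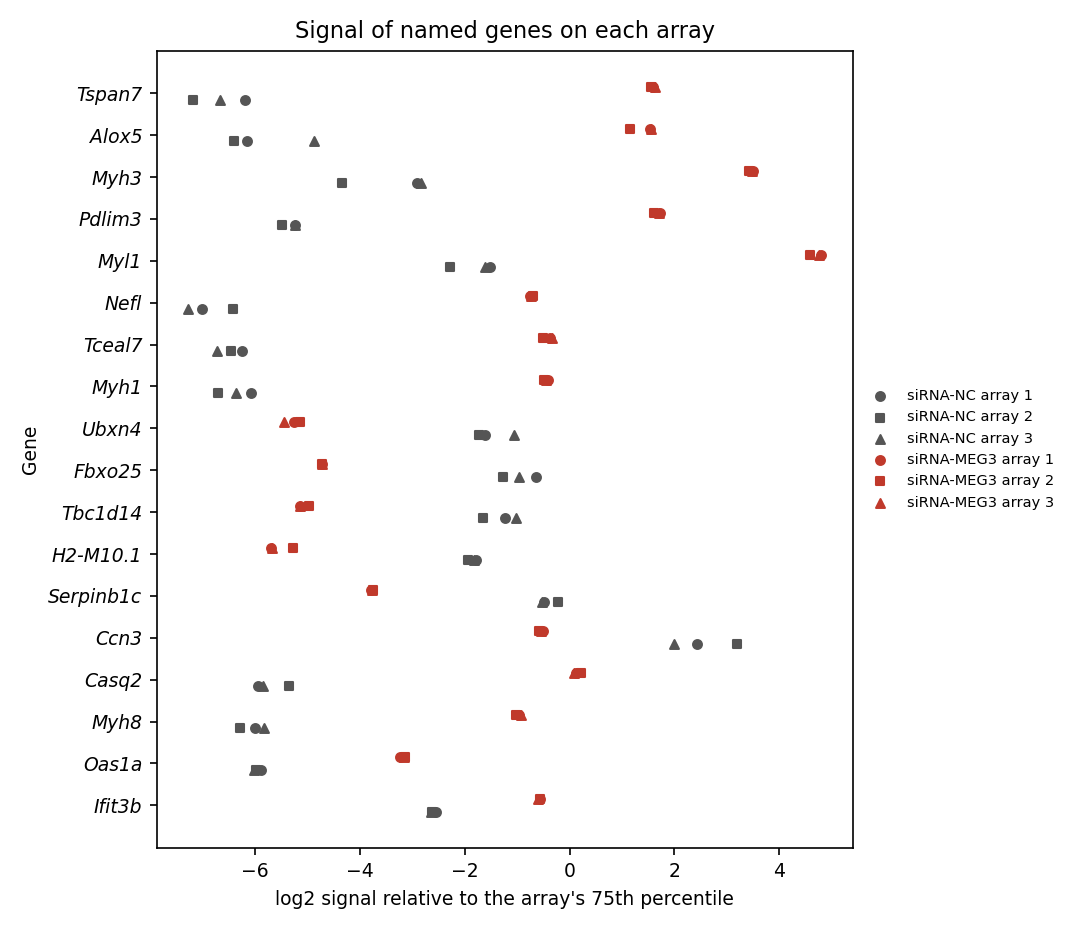
Points give each array's log2 signal relative to its own 75th percentile (x axis) for genes (y axis) named for the largest changes or as sarcomere or interferon genes, where well above background on at least 1 array of each group, with siRNA-NC arrays in grey and siRNA-MEG3 arrays in red; circles, squares and triangles are arrays 1, 2 and 3, without error bars. Genes of the largest changes were chosen for groups that do not overlap. The groups of Serpinb1c, above background on all arrays, lie apart by a log2 fold change of -3.39.

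Genes of G1/S and DNA replication were called higher as a list by camera with the preset correlation (adjusted p = 1.56e-06), but not with an estimated correlation (unadjusted p = 0.104, adjusted p = 1.00), and fry gave an adjusted p of 0.0743. Among 36 measured members, 32 had a positive fold change and the median was 0.75, a 1.68-fold difference. No member passed over all genes and 14 rose when adjusted over the list alone. Without siRNA-MEG3 array 2 the preset test gave an adjusted p of 0.0619, and over all other settings with the preset correlation it ranged from 3.69e-07 to 0.248, the highest values being those of the 2 normexp fits distorted by the speck. The member with the smallest p was the thymidylate synthase gene Tyms at 1.44 ± 0.22 (adjusted p = 0.0712, not passing). It stood at 1.51 without siRNA-MEG3 array 2, which leaves a lone siRNA-MEG3 sample. The 37 measured genes of G2 and M phase were not called (adjusted p = 0.783, median 0.27). In that list 2 genes passed, both lower: the mitotic kinase gene Cdk1 at -3.17 ± 0.21 and the chromosomal passenger kinase gene Aurkb at -3.08 ± 0.36 (adjusted p = 0.0205 and 0.0465). The other 2 probes of Cdk1 had a median of -0.38, far from that value, and with outlier spots kept Cdk1 stood at -0.92 (adjusted p = 0.180). Aurkb no longer passed without siRNA-NC array 1 (adjusted p = 0.0540) or without siRNA-MEG3 array 1 (0.0531), nor with normexp, the speck spots left out (-1.49, adjusted p = 0.0578). The difference between the lists was not tested.

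Interferon response genes were called higher as a list by camera with the preset correlation (adjusted p = 5.64e-05), but not with an estimated correlation (unadjusted p = 0.155, adjusted p = 1.00), and fry gave an adjusted p of 0.0743. Of 33 measured members 5 rose, none fell and 28 did not pass, while 13 rose when adjusted over the list alone, and the median was 0.68, a 1.60-fold difference. The antiviral genes Oas2 and Rsad2 were at least 5.15-fold and 4.76-fold higher (adjusted p = 0.0229 and 0.0280), with siRNA-NC below background on all arrays; Oas2 did not pass without siRNA-NC array 3 (adjusted p = 0.0611), and with normexp, the speck spots left out, both were smaller than these bounds, at 1.18 and 1.12 on the log2 scale, and did not pass (adjusted p = 0.128 and 0.118). Oas1a rose by 2.80 ± 0.21 and Ifit3b by 2.03 ± 0.21 (adjusted p = 0.0225 and 0.0381); Oas1a was well above background on 1 of 3 siRNA-NC arrays and did not pass in that normexp refit either (1.36, adjusted p = 0.0645).

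The lists of p53 targets, TGF-beta response and PRC2, set for naming, were called by neither camera nor fry. Of 29 measured p53 targets, Pmaip1 and Perp, both linked to cell death, rose by 2.72 ± 0.24 and 2.24 ± 0.23 (adjusted p = 0.0288 and 0.0369), and the list median was 0.00 (camera adjusted p = 1.00). Adjusted over the list alone 2 rose and 2 fell; the latter, Bax, also linked to cell death, and Gtse1, stood at -1.21 ± 0.21 and -1.27 ± 0.24 and did not pass over all genes (adjusted p = 0.0936 and 0.106; named after their values were seen). Of 27 TGF-beta response genes only Ccn2, a matricellular protein gene, passed, rising by 2.24 ± 0.22 (adjusted p = 0.0357; list median 0.28, camera adjusted p = 0.723). None of the 11 genes of Polycomb repressive complex PRC2 passed (camera adjusted p = 0.783). Phf1 had the smallest p there, at -0.96 ± 0.22 (adjusted p = 0.140), and the catalytic subunit gene Ezh2, singled out afterwards, stood at 0.23 ± 0.31.

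**Figure D3:**
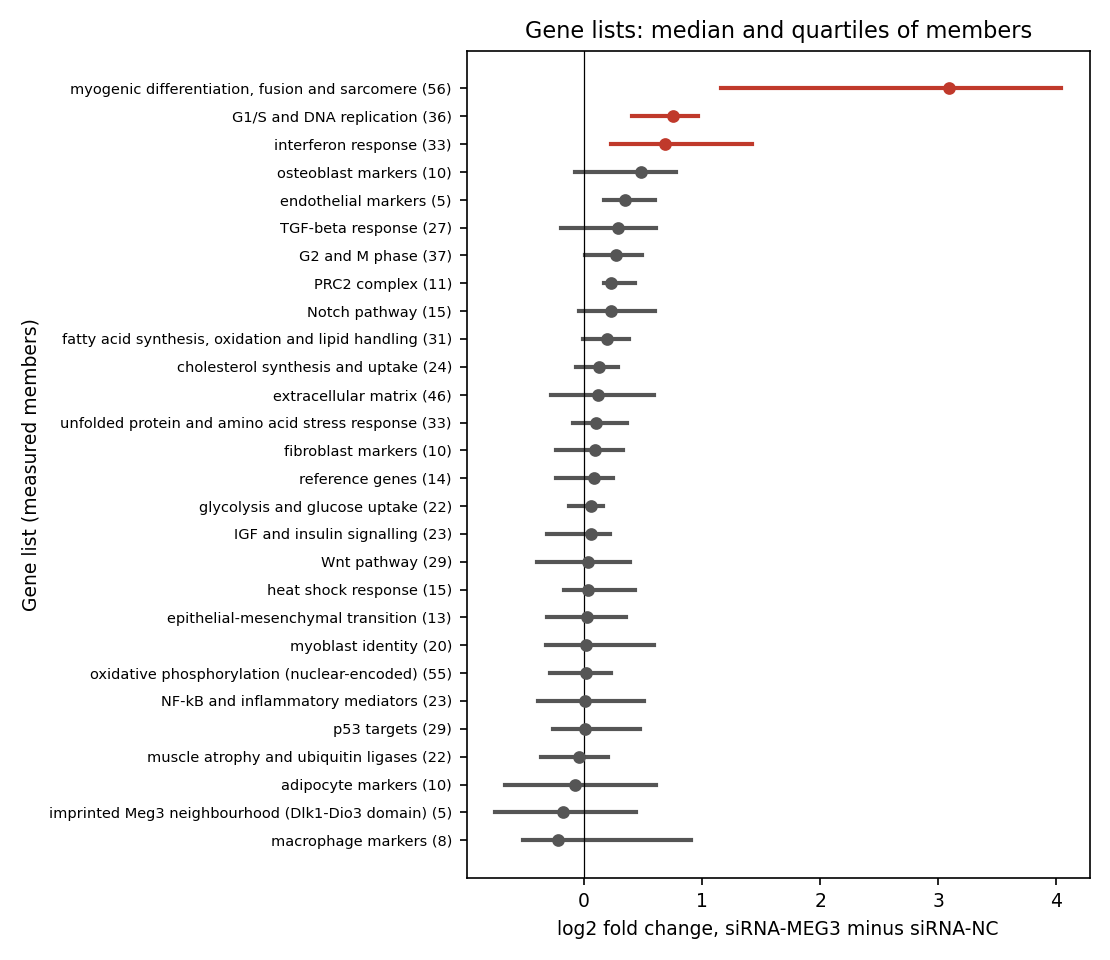
Points give the median log2 fold change of each of 28 gene lists (x axis, siRNA-MEG3 minus siRNA-NC) and bars the quartiles of its measured members, whose number stands in brackets; red marks the 3 lists called by camera with the preset correlation, none of which was called with an estimated correlation (smallest adjusted p = 0.134). The sarcomere list lies at 3.09, the other called lists at 0.75 and 0.68, and no list that was not called exceeds 0.48.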

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

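The alternatives that count the arrays differently, keep outlier spots, or refit normexp were chosen after the data were seen. The main counts were 253 genes higher, 98 lower and 3 lists called. As 6 samples the arrays gave 3906 and 2131, as 6 samples with the replicate number as a block 2197 and 1241, with only the rescan averaged (5 samples) 1232 and 825, and with the siRNA-MEG3 arrays as 1 sample 483 and 580. The pairs of near-identical arrays shrink the spread in the first 3 of these, by construction. In the 4-sample fit the replicate number as a block gave 161 and 52; the labels share only the numbers (every siRNA-MEG3 array correlated best with its own number, at r of at most 0.02), and the block left the 3 lists called.

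Without a filter on dim probes 33 and 1 passed, and with the labels' factor 57 were lower. Normexp with an offset of 50 called 0 higher and 0 lower by limma (1102 at an unadjusted p under 0.05) and 13 lists, and moved the median of all genes to 0.58; a maximum likelihood fit gave 0, 0 and 13 as well. A bright speck on siRNA-MEG3 array 2, with local background up to 264044 against a median of 21.5, had distorted its correction: the lowest percentile of corrected intensity was 1221 there and 58.1 to 60.1 elsewhere. Without its 18 spots normexp gave 239 higher, 150 lower and 3 lists. The median was 0.19 over all genes and 2.04 over the sarcomere list. Of these calls 61.4% were higher, against 72.1% with the processed signal, both with the 75th percentile scaling. Under the distorted fits Lyar (0.00716 and 0.000863), Rspo3 (0.27 and 0.26), Pdzrn4 (1.09 and 1.09), Aurkb (0.0585 and 0.0527), Dlk1 (1.54 and 1.54), Mirg (1.51 and 1.51) and Wdr25 (1.09 and 1.09) changed sign. Without the speck Dlk1 stood at 0.25, and leaving out each array put Wdr25 between -0.208 and 0.0674; neither gene passed the threshold in the 4-sample fit. Dlk1 stood at -2.52 without siRNA-MEG3 array 2, where the 1 siRNA-MEG3 sample left was below background.

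Leaving out each array gave 0 to 1399 higher, 0 to 1575 lower and 2 to 3 lists. The 0 came without siRNA-NC array 2 and the highest counts without siRNA-MEG3 array 2; each leaves 1 sample in a group, assumed to vary like the other group. Without siRNA-MEG3 array 2, and under the distorted normexp fits, the G1/S list was no longer called. No list was called with an estimated correlation (0), and fry called 3: the sarcomere list, myoblast identity (adjusted p = 0.00709) and fatty acid and lipid genes (0.0484), but not the G1/S and interferon lists (0.0743 for each). Quantile normalization, the authors' values, the stricter filter, the mean of probes, the variance trend and the fold limit kept both counts within 1.5 times, though not always the same genes: of the calls under the stricter filter 149 of 275 higher and 53 of 133 lower were called before, and under the variance trend 195 of 258 and 69 of 130, and the sarcomere list was called in all settings but the estimated correlation. No value is given for the Meg3 fold change in any setting, since no Meg3 probe was well above background on all arrays of a group. The slide block could not be fitted because no slide holds both groups. Dim probes limit what can be read: 69 of the higher genes were below background on all siRNA-NC arrays and 29 of the lower genes on all siRNA-MEG3 arrays, so their sizes are bounds.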

Other observations

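Some single genes moved in lists that camera did not call, and are named here after their values were seen. The inflammatory cytokine gene Il1b was at least 4.31-fold higher with siRNA-MEG3, with siRNA-NC below background on all arrays (limma adjusted p = 0.0357). The Notch target Hey1 rose by 2.21 ± 0.23 (log2 ± SE, n = 2 per group; adjusted p = 0.0379), the lipoprotein lipase gene Lpl by 1.89 ± 0.22 (adjusted p = 0.0467; 1.40 on its other probe) and the mannose receptor gene Mrc1 by 2.67 ± 0.21 (adjusted p = 0.0230). The matrix metalloproteinase gene Mmp3 stood at -2.60 ± 0.23 (adjusted p = 0.0274). Among the remaining lists, the medians and camera adjusted p were 0.12 and 0.783 for extracellular matrix, 0.03 and 0.975 for epithelial-mesenchymal transition, 0.01 and 0.952 for NF-kB mediators, 0.10 and 0.783 for the unfolded protein response, 0.03 and 1.00 for heat shock, 0.06 and 0.952 for glycolysis, and 0.01 and 0.783 for oxidative phosphorylation.

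They were 0.13 and 0.914 for cholesterol synthesis, 0.19 and 0.783 for fatty acid and lipid genes (which fry called, adjusted p = 0.0484), -0.05 and 0.808 for atrophy genes, 0.23 and 0.723 for Notch, 0.03 and 0.783 for Wnt, 0.06 and 0.783 for IGF and insulin signalling, and 0.08 and 1.00 for reference genes. Markers of other cell types were not called by camera either: 0.48 and 0.571 for osteoblasts, -0.08 and 1.00 for adipocytes, 0.09 and 0.821 for fibroblasts, -0.22 and 0.952 for macrophages and 0.35 and 0.783 for endothelium. Of 22 Hox genes tested, which mark positional identity, only Hoxb4 passed, at least 5.34-fold higher with siRNA-MEG3 and below background on all siRNA-NC arrays (adjusted p = 0.0164), and Fisher's exact test found no difference from the share among all genes (2-sided, p = 0.298).

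Of the tests below, only that of other probes was set before its result was seen, and single cases of it were known. siRNA-MEG3 arrays 1 and 3 shared the scatter of single spots (r = 0.98), as 2 scans of 1 array would, which argues against the same RNA on 2 separate arrays. siRNA-NC arrays 1 and 3 shared spot scatter no more than other pairs (r = 0.42), so they are separate arrays, and their variance ratio of 1.04 is what the same RNA hybridised to each would give. A candidate explanation is technical replication that the labels call biological.

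The rise of differentiation and sarcomere genes is the pattern most worth following up. The values argue against a shift between slides that depends on mean signal level. The list's median lay at the 100th percentile of 10000 random lists matched on mean brightness over both groups, whose highest median was 0.47. That brightness includes the rise itself, and no lists were matched on the siRNA-NC level alone. A culture, labelling or slide difference that follows the groups stays open, because 0 of the 3 scans held arrays of both groups. Loss of Meg3 may be the cause as the design intends. However, 0 of the Meg3 probes were well above background on all arrays of a group, so the knockdown could not be checked. Since slide and group coincide, loss of Meg3 cannot be told apart from any other difference that follows the groups. A chance difference in the state of the cultures is 1 of these. The 4 samples allow 3 splits into 2 and 2, too few for a share under 0.05: the real split called 351 genes, the highest of the others 0, and 1 split (the real one) called as many.

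Most of the genes called lower have only 1 tested probe or only an accession. No excess of called-lower probes was found in the dark patches of the siRNA-MEG3 arrays. Of the 98, 40 (40.8%) lay in a patch of either array and 58 outside. Among all tested probes 39.0% lay inside (2-sided Fisher's exact test, p = 0.756). A call needs both siRNA-MEG3 samples low, and 97 of the 98 (98.98%) lay outside the patches that both arrays shared. Only 2.34% of all tested probes lay inside those. A bound of most probes outside, set after a first comparison of shares was seen, was thus met almost in advance and decides nothing. The 1 probe inside is too few to compare its share with that of all tested probes (2-sided Fisher's exact test, p = 0.731). Loss or change of single probes rather than of transcripts stays open. Only 7 of the 98 genes had other probes, 9 in all, with a median of -0.97 against -2.90 on the called probes; of the 9, 8 went in the same direction as the called probe, 3 of them with at least 0.5 times its size. Of 41 other probes of called-higher genes, 37 went in the same direction, 26 of them with at least 0.5 times the size. Too few probes keep the question open.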
